A study of Mus musculus with 12 samples.

How the data were processed

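RNA was isolated with a silica-column kit (RNeasy) and sequenced from poly(A)-selected libraries that keep strand (TruSeq Stranded mRNA), per the labels' protocols. The 12 libraries fall into 4 groups of 3 by the compound and time in the labels, and the series design calls the cultures biological replicates. The deposited table gives, for each library, the raw read count of each gene by Entrez identifier, which the authors made with featureCounts on the mouse build mm10, per the submitters' processing notes. The aligner, the gene annotation, the strand setting of the counting and the tool's version are not given in the sources used here. Reads of a gene and of an overlapping or antisense gene may therefore not be separated, and genes with near-identical relatives are named as such. A column of gene lengths deposited with the counts was not used. Counts were taken as whole numbers with no normalization by the authors, per the file headers and the values themselves, and library columns were matched to samples by the descriptions in the labels.

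Of 27179 genes in the table, 25275 (93%) were matched to symbols in a RefSeq gene table of assembly GRCm38.p6, which is the coordinate system of mm10. The coordinates given are those of that table, counted from 1. The other 1904 identifiers held 1.04 to 1.62% of the reads of a library and stayed in the tests under their numbers. Library totals ran from 10147466 to 45903190 reads, a ratio of 4.52, and 3 reads correspond to 0.0654 to 0.296 CPM, which is a limit of counting alone. The 20 most abundant genes took 8.6% of the reads in the WM-2474 96 h group, 11.7% at 240 h, and 9.01% and 12.5% with WM-8014. Pairs of replicates were compared over genes with at least 20 reads, and their chi-square per degree of freedom was 2.1 to 7.13, more than sampling noise, so no library was counted as a duplicate.

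Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with filterByExpr by group, which left 14136 genes holding at least 99.93% of the reads of each library. Library sizes were scaled by TMM. A mean was fitted for each of the 4 groups over all 12 libraries, which share the estimate of the spread (common biological coefficient of variation 4.64%), and contrasts were tested with the robust quasi-likelihood F test, two-sided. Genes passed at a Benjamini-Hochberg adjusted p under 0.05. The contrasts were WM-8014 against WM-2474 at 96 h and at 240 h, the difference between those effects (interaction), and 240 h against 96 h under each compound. Adjusted p values and fold changes for single genes come from edgeR, at the default prior count of its fit, unless another tool is named. A prior count of 2 was used only for the log2 CPM of single libraries, which served the pairing and the direction in each culture. Standard errors are not an output of this test and were derived from the log2 fold change and its F statistic. Intervals of 95% were built from them.

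A set of 23 gene lists was tested with camera from limma 3.58.1 with a preset correlation of 0.01, adjusted over the lists. The lists were S phase and DNA replication, G2 and mitosis, cyclin-dependent kinase inhibitors, KAT6 complexes and MYST enzymes, p53 targets, secreted factors of senescent cells, extracellular matrix, contractile genes, Hox genes, other developmental transcription factors, interferon-stimulated genes, cholesterol synthesis, NRF2 and aryl hydrocarbon receptor targets, the integrated stress and unfolded protein responses, lysosome, imprinted genes, and markers of macrophages, endothelium, epithelium and mesothelium, skeletal muscle, neurons and glia, cartilage and bone, and adipocytes. Cdkn1a, Cdkn1c, Gdf15, Sesn2 and Dcn each stand on more than 1 list. The groups, the tests, the lists, the rule for named genes and most alternatives were fixed before the data were examined.

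The rule named 12 genes whatever their values (Kat6a, Kat6b, Cdkn2a, Cdkn2b, Cdkn1a, Cdc6, E2f2, Ezh2, Melk, Lmnb1, Mki67 and Top2a). At each time it added the 10 genes with the highest and the 10 with the lowest fold change among those that passed, had a mean log2 CPM of at least 1, moved the same way in all 3 same-numbered cultures and had a named symbol, and up to 4 genes with the smallest p in each list. For the interaction and for the changes over time it took the 5 highest and the 5 lowest. Some genes that the rule took are not reported here. Values of other genes in those last comparisons, which were named at 96 or 240 h, were added after their values were seen.

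Same-numbered cultures were tested for deviating together from their group means. At 96 h the correlations of the 3 pairs across genes were 0.14, 0.15 and 0.16, all over the limit of 0.1, so the numbers were taken to pair the libraries there. At 240 h they were 0.064, 0.24 and 0.048, and not all passed. Over all 18 same-numbered pairs of groups the mean was 0.11, and -0.055 for 36 other pairs. Deviations from a group mean cancel within the group, so the second value largely follows from the first and adds no support. The labels number the cultures and do not say what same-numbered cultures share. A fit with the culture number as a block was an alternative.

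The alternatives were DESeq2-type size factors, DESeq2 1.42.0, limma-voom, no filter on low counts, a stricter filter (CPM of at least 1 in 3 libraries and a mean log2 CPM of at least 1), a fit of only the groups compared, the block, and leaving out each library or each culture. For lists they were camera with an estimated correlation and fry, with size factors, filter, block and cultures as for genes. The ranges given for a list are over the settings of camera and leave out fry, which does not set a list against other genes. Thinning to the smallest library, leaving out the 20 most abundant genes, leaving out the WM-2474 96 h libraries of cultures 6 and 7, and the alternatives for lists over time were chosen after seeing the data.

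The fit was tested on simulated data for 14136 genes, of which 67, 67 and 66 were changed 1.25-, 1.5- and 2-fold in each comparison. These are far fewer than the genes called in the real data, so recovery and the share of false calls may differ there. At 96 h it recovered 50.75, 64.18 and 92.42% of genes changed 1.25-, 1.5- and 2-fold, and 8.61% of calls were on unchanged genes. At 240 h it recovered 62.69, 77.61 and 93.94% (4.29% of calls on unchanged genes), and for the interaction 28.36, 55.22 and 75.76% (3.64%). For the change over time the values were 59.7, 82.09 and 86.36% (10.1%) under WM-2474 and 50.75, 76.12 and 87.88% (9.49%) under WM-8014. The share of calls on unchanged genes was thus above the threshold of 0.05 at 96 h and for both changes over time. No sequencing batch is given in the labels, and no test for outlying libraries was run in groups of 3.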

Results

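Messenger RNA was sequenced from mouse embryonic fibroblasts, connective-tissue cells grown from wild-type C57BL/6 embryos at day 13.5 of gestation and kept at 3% oxygen. The cells received 10 µM WM-8014, given in the labels as an inhibitor of the MYST histone acetyltransferases, or 10 µM WM-2474, given as an inactive control, for 96 or 240 h. Cultures 5, 6 and 7 were sequenced in each of the 4 groups, which makes 12 libraries with 3 per group. Total counts per library were 10147466 to 45903190 in the WM-2474 96 h group and 13937538 to 14019263 in the WM-8014 96 h group. They were 19252762 to 23521441 in the WM-2474 240 h group and 10659860 to 31180476 in the WM-8014 240 h group. Values below are CPM, counts scaled to the library's TMM-adjusted total (mean ± SD, n = 3 cultures), and log2 fold changes from edgeR. The standard error (SE) of a log2 fold change was derived from it and the F statistic of its test. Each gene said to have risen or fallen with the compound moved that way in 3 of 3 same-numbered cultures, unless another number is given. All 12 libraries are labelled female, but each held transcripts of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, with Ddx3y at 96.2 to 124 CPM, and between 0 and 4 reads of Xist, the RNA that silences an X chromosome in female cells. These 5 genes were chosen after their values were seen.

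The first comparison set WM-8014 against WM-2474 at 96 h, at the same dose, and asked how dividing fibroblasts responded to the MYST inhibitor, including genes of cell-cycle exit. By camera with a preset correlation, genes for DNA replication, for mitosis and for cholesterol synthesis were lower with WM-8014 and lysosomal genes higher, and none of these 4 lists passed with an estimated correlation (adjusted p = 0.27, 0.17, 0.097 and 0.097). Cdkn2a, which encodes the cell-cycle inhibitor p16INK4a and the p53 activator ARF, rose 1.6-fold, from 87.8 ± 8.1 to 141 ± 7.5 CPM. The proliferation marker Mki67 fell 1.32-fold, from 259 ± 14 to 197 ± 11 CPM, and Dchs1, a cadherin of planar cell polarity, fell 3.33-fold, from 26.8 ± 0.3 to 8.03 ± 1.4 CPM. Of 14136 genes tested, 1544 rose and 1674 fell (22.8% in all), 59 and 120 of them by at least 2-fold.

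These counts depended on the libraries used. They were 977 and 1076 without the WM-2474 96 h library of culture 7, the deepest, and leaving cultures 5, 6 or 7 out of all groups gave 897, 1025 and 847 genes higher and 957, 1098 and 903 lower. The WM-2474 96 h libraries of cultures 6 and 7 stood apart in a few genes, chosen here after their values were seen. Misp3 was at 0.724 and 0.943 CPM there and at 79.9 to 285 CPM in the other 10 libraries, and Stag3 was at 1.81 and 2.5 CPM against 22.9 to 37.5 CPM. Ntn3 was at 11 and 13 CPM against 57.1 to 190 CPM, and Lrrn2 at 9.77 and 12.7 CPM against 26.5 to 42 CPM. Leaving out both libraries leaves 1 library in that group, which was assumed to vary like the other groups. Fewer libraries alone can end calls in that run. A call lost in it, as given for genes below, therefore does not show that the result rests on these 2 libraries.

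At 96 h, 34 of 48 genes of S phase and DNA replication fell, 2 rose and 12 did not pass the test (2 higher and 38 lower when adjusted over the list alone). The list's camera adjusted p was 1.3e-14, against adjusted p = 0.27 with an estimated correlation. Of 45 genes of G2 and mitosis, 44 fell and 1 did not pass (44 lower also when adjusted over the list alone). Camera gave 7.6e-29 as the adjusted p, against adjusted p = 0.17 with an estimated correlation. Chaf1a, a subunit of the histone chaperone CAF-1, fell from 53.6 ± 0.91 to 40.7 ± 1 CPM (log2 fold change -0.40, SE 0.0545, adjusted p = 2.91e-05). Uhrf1, which brings DNA methylation to replicated DNA, fell from 64.3 ± 4.8 to 45 ± 2.9 CPM (adjusted p = 6.61e-05). The mitotic kinase gene Plk1 fell from 74.1 ± 3 to 54.1 ± 2.1 CPM (adjusted p = 1.1e-05), and Top2a, the mitotic DNA topoisomerase, fell by 0.40 on the log2 scale (adjusted p = 9e-05). The replication licensing factor Cdc6 fell by 0.73 (adjusted p = 0.00066), the nuclear lamina gene Lmnb1 by 0.45 (adjusted p = 0.00234), the kinase gene Melk by 0.43 (adjusted p = 0.000265) and the histone methyltransferase gene Ezh2 by 0.40 (adjusted p = 0.000222). Without the WM-2474 96 h libraries of cultures 6 and 7 the calls of Cdc6 (adjusted p = 0.0738), Lmnb1 (0.115) and Ezh2 (0.124) were lost, with ranges of 1.82e-05 to 0.0738, 1.31e-06 to 0.115 and 1.38e-06 to 0.124 over the alternatives. E2f2, a transcription factor of the cell cycle, was at 1.97 ± 0.52 CPM with WM-2474 and 1.45 ± 0.04 CPM with WM-8014, a log2 difference of -0.55 with a 95% interval of -1.03 to -0.07 (adjusted p = 0.0933, lower in 2 of 3 cultures, 0.0417 without the WM-2474 96 h library of culture 5). Over the alternative settings this p was 0.0417 to 0.964.

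Of 7 genes of cyclin-dependent kinase inhibitors, 3 rose, 2 fell and 2 did not pass at 96 h (3 higher and 3 lower when adjusted over the list alone), and the list as a whole did not pass (camera adjusted p = 0.55, direction up, with a median log2 fold change of -0.22 and a mean of -0.03). Cdkn2a (chromosome 4, 89274473 to 89294619, mm10) rose by a log2 fold change of 0.68 (SE 0.0571, adjusted p = 8.27e-07), and its neighbour Cdkn2b (89306289 to 89311032), which encodes p15INK4b, rose from 97.7 ± 5.2 to 115 ± 4.8 CPM (0.24, SE 0.0429, adjusted p = 0.000395). The count is per gene, so the INK4a and ARF transcripts of Cdkn2a were not separated. Cdkn1a, which encodes p21, rose by 0.11 (adjusted p = 0.0405), and this call was lost without the WM-2474 96 h library of culture 5 (0.136) or 7 (0.127) and without the WM-8014 96 h library of culture 5 (0.062), 6 (0.106) or 7 (0.0907), and with DESeq2 (0.073) or its size factors (0.053), with a range of 0.02 to 0.182 over the alternative settings. Cdkn1b, which encodes p27, fell by 0.48 (adjusted p = 3.13e-05), and Cdkn2d fell by 0.32 (adjusted p = 0.00442, 0.0594 without the WM-2474 96 h library of culture 7). This p ran from 0.00266 to 0.293 over the alternative settings. Of 11 genes of the KAT6 complexes and other MYST enzymes, 1 rose, 1 fell and 9 did not pass (1 and 1 also when adjusted over the list alone; camera adjusted p = 0.93, median -0.01 and mean 0.01). Brpf1, a scaffold of the KAT6 complexes, fell from 45.4 ± 1.2 to 34.7 ± 1.3 CPM (adjusted p = 4.6e-05), and Kat6b rose by 0.20 (adjusted p = 0.00743, 0.0542 without the WM-8014 96 h library of culture 5, 0.13 without culture 5 in all groups). Across the alternative settings the same p was 0.00332 to 0.13. The calls of Cdkn1b (adjusted p = 0.0521) and Kat6b (0.113) were lost without the WM-2474 96 h libraries of cultures 6 and 7, the former in a range of 1.75e-08 to 0.0521. Kat6a differed by -0.07 between the compounds (95% interval -0.15 to 0.02, adjusted p = 0.256). The plot of CPM per library shows 8 of the genes described here.

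**Figure D1:**
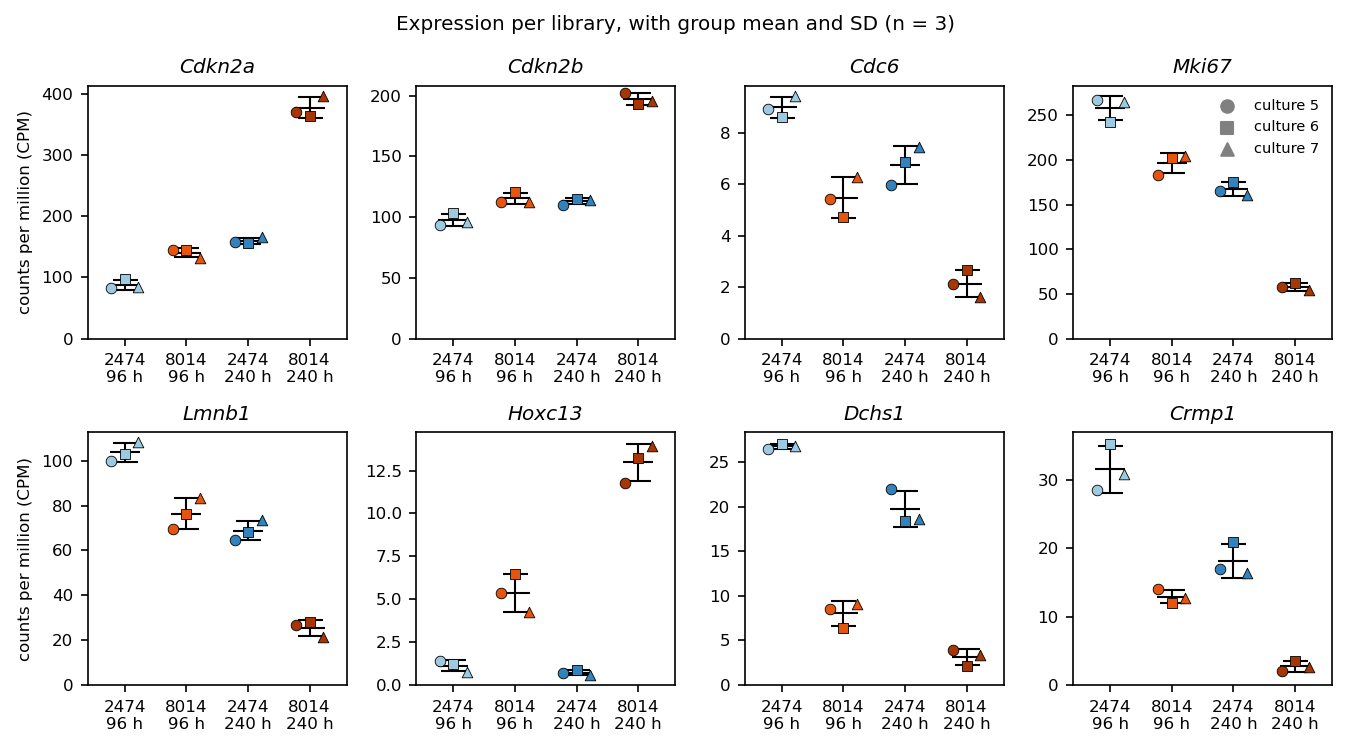
CPM in each of the 12 libraries for Cdkn2a, Cdkn2b, Cdc6, Mki67, Lmnb1, Hoxc13, Dchs1 and Crmp1, by compound (the axis shows each code name without its prefix) and time, with 1 marker shape per culture and bars for the group mean and SD (n = 3). Mean Cdkn2a was 87.8 and 141 CPM at 96 h and 160 and 378 CPM at 240 h with WM-2474 and WM-8014, while mean Mki67 was 259 and 197 CPM at 96 h and 167 and 57.9 CPM at 240 h.

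Among the genes with the highest fold changes at 96 h, Hoxc13 (Entrez 15422, chromosome 15, 102921131 to 102928814) rose 5.54-fold, from 1.13 ± 0.33 to 5.37 ± 1.1 CPM (log2 fold change 2.47, SE 0.215, adjusted p = 1.78e-07). Foxf1 (Entrez 15227, chromosome 8, 121084386 to 121088154), a forkhead factor of the mesenchyme, rose 3.02-fold, from 2.26 ± 0.17 to 6.79 ± 0.3 CPM. Angptl4, a secreted inhibitor of lipoprotein lipase, rose 2.88-fold, and Ugt1a6a, whose reads may be shared with other transcripts of the Ugt1a locus, rose 2.89-fold. Cd53, a tetraspanin, rose from 0.756 ± 0.25 to 2.38 ± 0.35 CPM, the integrin gene Itgb7 from 2.93 ± 1 to 8.54 ± 2.5 CPM, and H2-DMb1, which resembles H2-DMb2 and may share reads with it, from 0.844 ± 0.25 to 2.9 ± 0.34 CPM. For Itgb7 the adjusted p was 0.0868 without the WM-2474 96 h libraries of cultures 6 and 7, in a range of 2.87e-08 to 0.0868 over the alternative settings. The genes Ptprc and Adgre1, markers of leukocytes and macrophages on the lists, were at 0.317 ± 0.17 and 0.0904 ± 0.078 CPM in the same WM-8014 libraries. Stag3, Ntn3 and Cxcr6 were also among the 10 highest, with adjusted p of 0.0436, 0.041 and 0.0402. These became 0.111, 0.118 and 0.0824 without the WM-2474 96 h library of culture 6, 0.188, 0.163 and 0.199 without that of culture 7, 0.116, 0.121 and 0.108 without the WM-8014 96 h library of culture 5, and 0.0782, 0.0985 and 0.13 without that of culture 6. Without the WM-2474 96 h library of culture 5 the log2 fold change of Stag3 went from 2.29 to 3.70 and that of Ntn3 from 2.06 to 3.04, and without that of culture 7 the log2 fold change of Stag3 was 1.42. Stag3 was also lost without the WM-8014 96 h library of culture 7 (0.0933) and with the culture number as a block (0.0514), and Cxcr6 without the WM-2474 96 h library of culture 5 (0.0699). Without both WM-2474 96 h libraries of cultures 6 and 7, Stag3 (0.0998) and Ntn3 (0.485) were lost, with log2 fold changes of 0.41 and 0.66, while that of H2-DMb1 was 2.36. With no filter on low counts the 3 values were 0.0599, 0.0565 and 0.0777, and with all libraries thinned to the smallest total 0.0982, 0.0628 and 0.0646. The ranges over the alternative settings were 4.65e-11 to 0.388, 0.000183 to 0.485 and 0.000105 to 0.494.

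Among the genes with the lowest fold changes, Dchs1 (Entrez 233651, chromosome 7, 105752989 to 105788355) had a log2 fold change of -1.74 (SE 0.128, adjusted p = 1.78e-07). Frem1, a basement membrane protein, fell 3.39-fold, from 3.12 ± 0.76 to 0.973 ± 0.14 CPM, and Hhip, which binds hedgehog ligands, fell 2.94-fold, from 6.81 ± 1.6 to 2.24 ± 0.65 CPM. Rab3c, a small GTPase of secretion, fell 2.79-fold, Nell2 2.66-fold, Nexmif 2.57-fold and the imprinted gene Nnat 2.46-fold. For Nell2 the adjusted p was 0.159 without the WM-2474 96 h libraries of cultures 6 and 7, in a range of 2.59e-06 to 0.159. Heyl, a Notch target gene, was at 0.511 ± 0.28 CPM with WM-2474 and 0.0681 ± 0.068 CPM with WM-8014, where it had 3 reads over the group (adjusted p = 0.00427, 0.0628 without the WM-2474 96 h library of culture 7). The p ranged from 0.000468 to 0.651 over the alternative settings. Cpxm2 and Hey2 were also in this set, with adjusted p of 0.00152 and 0.0144 that became 0.0618 and 0.137 without the same library, and for Hey2 0.091 and 0.0611 without the WM-8014 96 h library of culture 5 or 7, with ranges of 0.000213 to 0.674 and 0.00422 to 0.674 over the alternative settings.

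Of 25 genes of cholesterol synthesis at 96 h, all but 1 fell (25 lower when adjusted over the list alone). Camera gave 5.1e-22 as the adjusted p, against adjusted p = 0.097 with an estimated correlation. Lss, the lanosterol synthase gene, fell from 264 ± 5.5 to 208 ± 4.9 CPM (log2 fold change -0.34, SE 0.0347, adjusted p = 1.03e-06), and the phosphomevalonate kinase gene Pmvk fell from 74.6 ± 1.9 to 52 ± 5.8 CPM. Of 29 lysosomal genes, 23 rose and 6 did not pass (24 higher when adjusted over the list alone). Camera gave 1.3e-14 as the adjusted p, against adjusted p = 0.097 with an estimated correlation. The protease gene Ctsk rose from 91.4 ± 4.2 to 139 ± 8.2 CPM (adjusted p = 5.67e-06) and Lgmn from 69.1 ± 2.2 to 93.2 ± 4.8 CPM (adjusted p = 1.63e-06). Of 37 extracellular matrix genes, 14 rose, 4 fell and 19 did not pass (15 and 6 when adjusted over the list alone; median 0.13, mean -0.02, direction up, camera adjusted p = 0.075, 0.0273 with the culture number as a block, 0.0123 without culture 6, 0.0293 without culture 7). Over the alternative settings this p was 0.0123 to 0.632. The fibrillin gene Fbn1 rose from 1480 ± 33 to 1930 ± 40 CPM, and the fibulin gene Fbln1 fell from 82.4 ± 2.2 to 58.8 ± 1.7 CPM. Of 17 contractile and myofibroblast genes, 10 fell, 1 rose and 6 did not pass (the same counts when adjusted over the list alone). Camera gave 0.0015 as the adjusted p, against adjusted p = 0.57 with an estimated correlation. Acta2, the smooth muscle actin gene, fell by 0.28 on the log2 scale (adjusted p = 0.000112) and the tropomyosin gene Tpm1 by 0.29 (adjusted p = 0.000147).

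At 96 h, 5 of 30 factors secreted by senescent cells rose, 2 fell and 23 did not pass (5 and 2 when adjusted over the list alone; camera adjusted p = 0.32). Angptl4 rose, as above, and Igfbp5, an insulin-like growth factor binding protein, fell from 1320 ± 80 to 596 ± 100 CPM (log2 fold change -1.15, SE 0.127, adjusted p = 0.000386). Of 28 p53 target genes, 3 rose, 4 fell and 21 did not pass (3 and 5 when adjusted over the list alone; camera adjusted p = 0.54), and Pmaip1, which encodes the cell-death factor NOXA, fell by 0.74 (adjusted p = 1.31e-05). Of 22 genes of the integrated stress and unfolded protein responses, 3 rose, 5 fell and 14 did not pass (5 and 5 when adjusted over the list alone; camera adjusted p = 0.72), with the secreted chaperone-like factor Manf at -0.30 (adjusted p = 8e-06) and the transcription factor gene Atf5 at 0.26 (adjusted p = 0.000123). Of 15 targets of NRF2 and the aryl hydrocarbon receptor, 3 rose and 12 did not pass (6 higher and 1 lower when adjusted over the list alone; camera adjusted p = 0.26), and Nqo1 rose by 0.48 (adjusted p = 0.000347). G6pdx was at 78.3 ± 3.8 and 85.7 ± 3.7 CPM (adjusted p = 0.0538, 0.028 with the block, 0.0324 without the WM-2474 96 h library of culture 5, 0.045 without the WM-8014 96 h library of culture 7). This p ran from 0.028 to 0.737 over the alternative settings. Of 23 interferon-stimulated genes, 4 rose and 19 did not pass (4 higher also when adjusted over the list alone). Camera gave 0.0021 as the adjusted p, against adjusted p = 0.57 with an estimated correlation and 0.103 without culture 5. Across the alternative settings the same p was 5.85e-09 to 0.571. Gbp2 rose from 7.33 ± 0.88 to 11.3 ± 0.48 CPM (adjusted p = 0.000419). Its call and that of Nqo1 were lost without the WM-2474 96 h libraries of cultures 6 and 7 (adjusted p = 0.128 and 0.108), with ranges of 1.63e-05 to 0.128 and 8.83e-06 to 0.108.

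Developmental and imprinted genes went both ways at 96 h. Of 33 Hox genes, 3 rose, 8 fell and 22 did not pass (3 and 10 when adjusted over the list alone; median -0.17, mean 0.05, direction down, camera adjusted p = 0.32). Hoxb13 was at 0.387 ± 0.18 CPM with WM-2474 and 3.03 ± 0.86 CPM with WM-8014 (log2 fold change 2.65, SE 0.301, adjusted p = 3.87e-06, with 3.38 without the WM-2474 96 h library of culture 7 and 3.41 without those of cultures 6 and 7), while Hoxc8 fell by 0.32 (adjusted p = 0.000215, 0.0918 without the WM-2474 96 h libraries of cultures 6 and 7, in a range of 7.78e-07 to 0.0918). Of 45 other developmental transcription factors, 3 rose, 11 fell and 31 did not pass (3 and 12 when adjusted over the list alone; camera adjusted p = 0.081, 0.00233 with the block, 0.0142 without culture 6). The p ranged from 0.00233 to 0.423 over the alternative settings. Beside Foxf1, its neighbour on chromosome 8, Foxc2 (121116171 to 121118895), fell from 38.9 ± 1.3 to 29 ± 0.81 CPM (adjusted p = 2.46e-05). Of 15 imprinted genes, 1 rose, 4 fell and 10 did not pass (1 and 4 also when adjusted over the list alone; median 0.02, mean -0.17, direction down, camera adjusted p = 0.43), and Peg3 fell from 256 ± 5.9 to 188 ± 15 CPM (adjusted p = 0.00028).

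At 96 h, 3 of 14 listed macrophage markers could be measured and 1 rose (3 higher when adjusted over the list alone; camera adjusted p = 0.15). This was the lysozyme gene Lyz2, at 1.92 ± 0.31 and 2.99 ± 0.73 CPM, with an adjusted p of 0.0482 that became 0.119, 0.0664 or 0.135 without the WM-2474 96 h library of culture 5, 6 or 7 and 0.112 or 0.252 without the WM-8014 96 h library of culture 5 or 7. It was 0.132 with DESeq2, 0.0538 with limma-voom, 0.0512 with no filter on low counts, 0.0504 without the 20 most abundant genes and 0.194 without both WM-2474 96 h libraries of cultures 6 and 7. Over the alternative settings this p was 0.0218 to 0.366. Of 6 adipocyte markers, 2 rose and 4 did not pass (3 higher when adjusted over the list alone). Camera gave 0.0035 as the adjusted p, against adjusted p = 0.1 with an estimated correlation and 0.081 with no filter on low counts. This p ran from 0.00177 to 0.101 over the alternative settings. The markers that rose were the lipid droplet gene Plin4, which rose 2.11-fold to 22 ± 2.1 CPM (adjusted p = 8.27e-07), and the fatty acid carrier gene Fabp4, which rose 2.17-fold to 4.55 ± 0.94 CPM (adjusted p = 0.000501). Without the WM-2474 96 h libraries of cultures 6 and 7 the call of Fabp4 was lost (adjusted p = 0.199, in a range of 1.89e-05 to 0.199). Of 11 neural and glial markers, 1 rose, 3 fell and 7 did not pass (1 and 4 when adjusted over the list alone; camera adjusted p = 0.55). The calls, of Stmn2, Map2, Nes and Gap43, were each lost in some alternative settings. Of 11 cartilage and bone markers, 2 rose, 1 fell and 8 did not pass (2 and 1 when adjusted over the list alone; camera adjusted p = 0.88), and Runx2, the osteoblast factor, fell by 0.20 (adjusted p = 0.00687, 0.132 without those 2 WM-2474 96 h libraries, in a range of 0.00213 to 0.132). Col11a2 differed by -0.52 (adjusted p = 0.0796, 0.0372 with the block). Across the alternative settings the same p was 0.0372 to 0.291. Of 6 endothelial markers 1 fell (1 also when adjusted over the list alone; camera adjusted p = 0.4), of 7 epithelial and mesothelial markers 1 fell (1 also when adjusted over the list alone; median 0.08, mean -0.21, direction down, camera adjusted p = 0.43), and of 6 skeletal muscle markers 0 passed (0 also when adjusted over the list alone; camera adjusted p = 0.74, median -0.00, mean 0.01, direction up). The endothelial call, of Kdr, was lost in some alternative settings. At an unadjusted p under 0.05, edgeR gave 1 skeletal muscle marker, and DESeq2 and limma-voom called 0 and 0. The epithelial keratin gene Krt18 was at 2.02 ± 0.64 and 0.815 ± 0.0034 CPM (adjusted p = 0.00126, 0.0678 without culture 7, and 0.000354 to 0.0678 over the alternative settings), and Wt1 at 1.24 ± 0.78 and 0.634 ± 0.35 CPM (adjusted p = 0.142, 0.03 with the block, 0.021 without the WM-2474 96 h library of culture 6). The p ranged from 0.021 to 0.788 over the alternative settings.

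At 240 h the same comparison asked what longer treatment did. Mki67 fell 2.88-fold, from 167 ± 7.5 to 57.9 ± 4.1 CPM, and the lists of replication and mitosis had median log2 fold changes of -0.83 and -1.14 (adjusted p = 0.076 and 0.035 with an estimated correlation). Cdkn2a rose 2.36-fold, from 160 ± 5 to 378 ± 17 CPM, and Cdkn2b 1.74-fold, from 113 ± 2.5 to 197 ± 4.9 CPM. Lmnb1, whose product lines the nuclear envelope, fell 2.69-fold, from 68.8 ± 4.4 to 25.5 ± 3.6 CPM. Prelp, a small leucine-rich matrix protein, rose from 117 ± 17 to 567 ± 12 CPM, while the basement membrane collagen gene Col15a1 fell from 66.6 ± 1.3 to 13.4 ± 2.1 CPM. Of 14136 genes, 2996 rose and 3031 fell (42.6% in all), 237 and 473 of them by at least 2-fold.

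**Figure D2:**
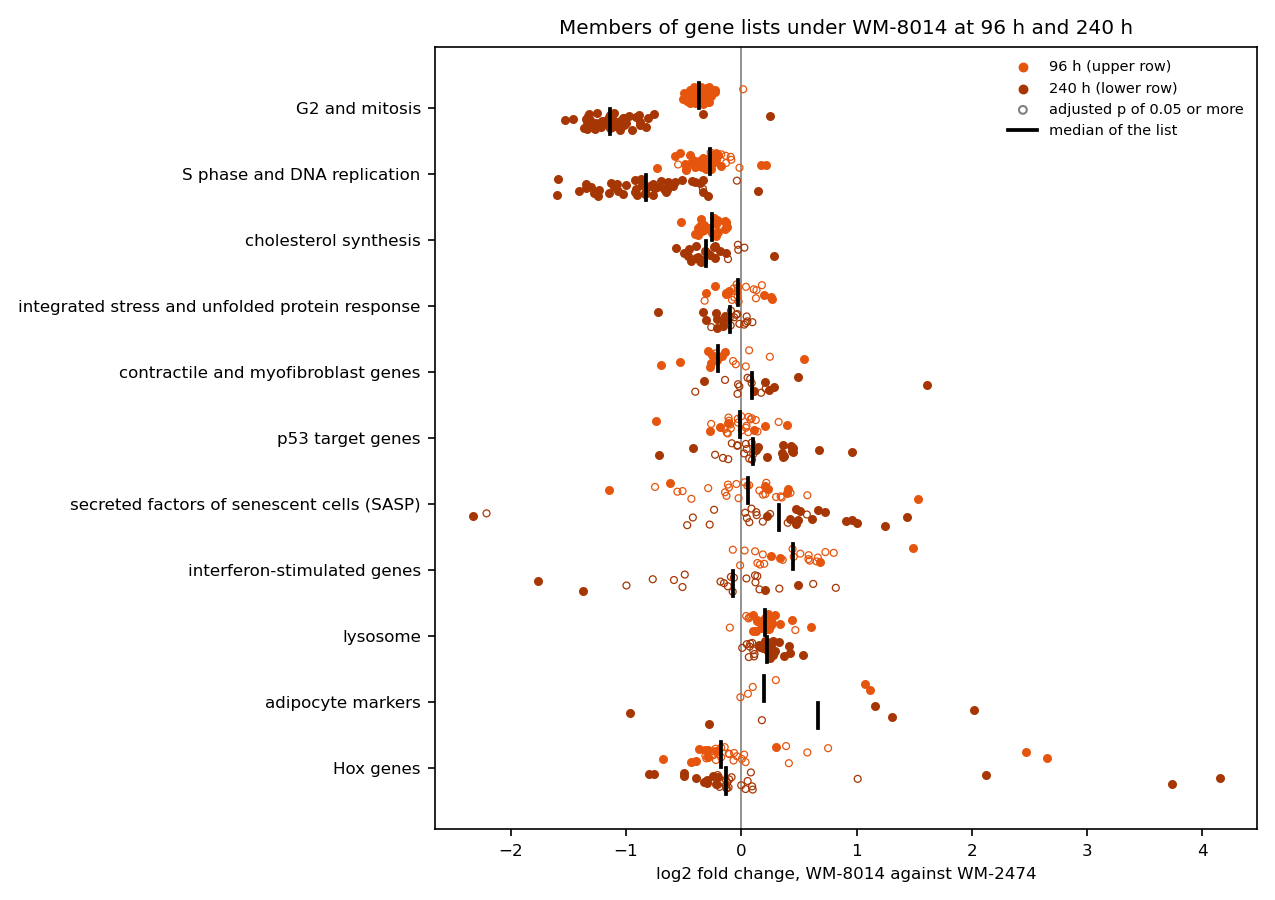
Log2 fold change of each measured member of 11 gene lists with WM-8014 against WM-2474 at 96 h and 240 h. Filled points passed an adjusted p of 0.05 and black bars are list medians, which for G2 and mitosis were -0.37 at 96 h and -1.14 at 240 h.

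At 240 h, 45 of 48 genes of S phase and DNA replication fell, 1 rose and 2 did not pass (1 and 46 when adjusted over the list alone). Camera gave 2.1e-36 as the adjusted p, against adjusted p = 0.076 with an estimated correlation. Of 45 genes of G2 and mitosis, 44 fell and 1 rose (the same counts when adjusted over the list alone). Camera gave 7.4e-81 as the adjusted p, and adjusted p = 0.035 with an estimated correlation. Cdc6 fell 3.04-fold, from 6.74 ± 0.74 to 2.13 ± 0.52 CPM (log2 fold change -1.60, SE 0.162, adjusted p = 6.82e-08), Uhrf1 fell 3-fold, from 45.1 ± 2.8 to 14.6 ± 2.1 CPM (adjusted p = 1.07e-10), and E2f2 fell from 1.85 ± 0.21 to 0.718 ± 0.19 CPM (adjusted p = 0.000174). Plk1 fell by 1.33 on the log2 scale (adjusted p = 1.97e-12), Top2a by 1.32 (adjusted p = 4.16e-11), Melk by 1.32 (adjusted p = 1.35e-10), Ezh2 by 0.97 (adjusted p = 1.04e-09) and the maintenance DNA methyltransferase gene Dnmt1 by 0.66 (adjusted p = 3.54e-11). Of 7 kinase inhibitor genes, 3 rose, 3 fell and 1 did not pass (3 and 4 when adjusted over the list alone; median -0.63, mean -0.19, direction up, camera adjusted p = 0.3). Cdkn2a rose by 1.24 (SE 0.0534, adjusted p = 1.69e-11), Cdkn2b by 0.80 (SE 0.0411, adjusted p = 5.21e-12) and Cdkn1a by 0.37 (SE 0.0373, adjusted p = 6.04e-08), while Cdkn1b fell by 0.93 and Cdkn2c, which encodes p18INK4c, by 1.28. Of 11 genes of the KAT6 complexes and MYST enzymes, 2 rose, 2 fell and 7 did not pass (2 and 2 also when adjusted over the list alone; median -0.03, mean 0.00, direction down, camera adjusted p = 0.99). Kat6a fell by 0.21 (adjusted p = 0.000233) and Kat6b rose by 0.28 (adjusted p = 9.67e-05). Brpf3 rose by 0.25 (adjusted p = 0.000628), and at 96 h its difference of 0.14 had an adjusted p of 0.0603, which was 0.0352 with the block, 0.0138 without the WM-2474 96 h library of culture 5, and 0.0138 to 0.971 over the alternative settings.

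The highest fold change of the 240 h set was that of Hoxc13, which rose 17.7-fold, from 0.727 ± 0.15 to 13 ± 1.1 CPM (log2 fold change 4.15, SE 0.196, adjusted p = 2.13e-12). H2-DMb1 rose 5.74-fold, Foxf1 4.99-fold, Cd53 4.23-fold to 7.99 ± 1.3 CPM, Plin4 4.06-fold to 14.2 ± 1.6 CPM, and Cxcr6, a chemokine receptor, 3.8-fold, from 5.46 ± 1 to 20.7 ± 5.8 CPM. Prelp rose 4.87-fold (adjusted p = 2.28e-06), and Sdsl, an enzyme of serine metabolism, 3.62-fold. Aldh1a7 and Serpina3n, each with near-identical relatives whose reads may be shared, rose 5.87-fold and 3.8-fold. Heyl fell 17.3-fold, from 6.27 ± 1.6 to 0.373 ± 0.053 CPM (adjusted p = 1.08e-09), Frem1 8.39-fold to 0.342 ± 0.064 CPM, and Dchs1 6.82-fold to 3.14 ± 0.91 CPM (log2 fold change -2.77, SE 0.153). Crmp1 (Entrez 12933, chromosome 5, 37242058 to 37292163), a cytoskeletal regulator of neurons, fell 6.15-fold, from 18.1 ± 2.5 to 2.73 ± 0.76 CPM (adjusted p = 3.12e-10), Col15a1 4.92-fold (adjusted p = 1.08e-11) and Igfbp5 5.04-fold, from 1020 ± 56 to 204 ± 24 CPM. Itih5 fell 5.29-fold and Shfl 4.96-fold. Adamts15 had a log2 fold change of -2.62, and -3.22 without the WM-8014 240 h library of culture 7. That of Enpep was -2.29, and -1.64 without the WM-8014 240 h library of culture 6 and -1.68 with all libraries thinned to the smallest total.

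At 240 h, 13 of 28 p53 targets rose, 2 fell and 13 did not pass (14 and 2 when adjusted over the list alone). Camera gave 0.019 as the adjusted p, against adjusted p = 0.47 with an estimated correlation and 0.0514 without culture 7. Over the alternative settings this p was 0.00343 to 0.473. Mdm2, which marks p53 for degradation, rose from 220 ± 11 to 297 ± 16 CPM (log2 fold change 0.44, SE 0.0409, adjusted p = 2.24e-08), and Ccng1 rose from 937 ± 7.9 to 1200 ± 29 CPM (adjusted p = 3.32e-08), while Ckap2, a spindle gene on the same list, fell by 0.71. Of 30 secreted factors of senescent cells, 14 rose, 1 fell and 15 did not pass (16 and 2 when adjusted over the list alone). Camera gave 0.019 as the adjusted p, against adjusted p = 0.3 with an estimated correlation. Gdf15, a stress cytokine, rose from 7.27 ± 0.95 to 14.3 ± 0.91 CPM (adjusted p = 1.75e-07), and the urokinase gene Plau from 146 ± 4.9 to 241 ± 30 CPM (adjusted p = 3.03e-05). Of 22 stress response genes, 9 fell and 13 did not pass (9 lower also when adjusted over the list alone). Camera gave 0.021 as the adjusted p, against adjusted p = 0.34 with an estimated correlation and 0.0683 without culture 6. This p ran from 0.00101 to 0.342 over the alternative settings. The amino acid transporter gene Slc7a5 fell from 295 ± 17 to 179 ± 12 CPM (adjusted p = 1.91e-10) and the chaperone gene Hspa5 from 1010 ± 17 to 812 ± 14 CPM. Of 15 targets of NRF2 and the aryl hydrocarbon receptor, 7 rose, 4 fell and 4 did not pass (7 and 4 also when adjusted over the list alone; camera adjusted p = 0.26). Nqo1 rose 1.95-fold to 45 ± 4.6 CPM and Hmox1, the heme oxygenase gene, 1.82-fold to 199 ± 19 CPM, while the glutathione reductase gene Gsr fell 1.49-fold.

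At 240 h, 20 of 25 cholesterol genes fell, 1 rose and 4 did not pass (20 and 1 also when adjusted over the list alone). Camera gave 3e-07 as the adjusted p, against adjusted p = 0.3 with an estimated correlation. Lss fell from 107 ± 3.5 to 75.8 ± 0.9 CPM (adjusted p = 1.12e-09). Of 29 lysosomal genes, 20 rose and 9 did not pass (20 higher also when adjusted over the list alone). Camera gave 1.7e-07 as the adjusted p, against adjusted p = 0.23 with an estimated correlation. The cathepsin gene Ctsd rose from 993 ± 24 to 1440 ± 30 CPM (adjusted p = 1.38e-10). Of 37 matrix genes, 10 rose, 11 fell and 16 did not pass (13 and 11 when adjusted over the list alone; camera adjusted p = 0.86). Thbs1, which encodes thrombospondin 1, rose from 17600 ± 400 to 24600 ± 130 CPM, and Fbln1 fell from 66.2 ± 6.1 to 26.7 ± 0.53 CPM. Of 17 contractile genes, 6 rose, 1 fell and 10 did not pass (6 and 1 also when adjusted over the list alone; camera adjusted p = 0.095, 0.00383 without culture 7). Across the alternative settings the same p was 0.00383 to 0.749. The intermediate filament gene Des rose from 30.2 ± 3.5 to 92.6 ± 12 CPM (adjusted p = 1.01e-07), and Tpm2 rose 1.41-fold. Smtn, the smoothelin gene, fell from 170 ± 8 to 136 ± 8.2 CPM. Of 23 interferon-stimulated genes, 2 rose, 2 fell and 19 did not pass (1 and 0 when adjusted over the list alone; median -0.07, mean -0.18, direction up, camera adjusted p = 0.89), and Ifit2 rose by 0.50 (adjusted p = 1.32e-05). The other calls, of Oasl2, Cmpk2 and Ddx58, were each lost in some alternative settings. Their adjusted p ranged from 0.0063 to 0.185, 0.0299 to 0.155 and 0.00378 to 0.348.

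Of 33 Hox genes at 240 h, 3 rose, 11 fell and 19 did not pass (3 and 11 also when adjusted over the list alone; median -0.13, mean 0.15, direction down, camera adjusted p = 0.65). Hoxb13 was at 0.236 ± 0.13 and 3.18 ± 0.27 CPM (log2 fold change 3.74, SE 0.346, adjusted p = 1.85e-08), and Hoxd4 fell from 10.2 ± 0.011 to 5.83 ± 0.57 CPM (adjusted p = 1.02e-05). Of 45 other developmental factors, 9 rose, 13 fell and 23 did not pass (9 and 13 also when adjusted over the list alone; camera adjusted p = 0.65), and Osr1 fell 1.69-fold. Of 15 imprinted genes, 3 rose, 6 fell and 6 did not pass (4 and 7 when adjusted over the list alone; camera adjusted p = 0.058, 0.0253 with the block, 0.0147 without culture 6, 0.0213 without culture 7). The p ranged from 0.0147 to 0.473 over the alternative settings. Peg3 fell 2.11-fold to 67.9 ± 3.9 CPM, Igf2r 1.31-fold and Dlk1 3.59-fold to 57.9 ± 17 CPM.

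Of the marker lists at 240 h, 2 of 3 measured macrophage markers rose (3 when adjusted over the list alone; camera adjusted p = 0.079, 0.039 without culture 5, and 0.039 to 0.298 over the alternative settings), Csf1r from 2.24 ± 0.71 to 5.42 ± 0.8 CPM and Lyz2 from 0.759 ± 0.15 to 2.01 ± 0.52 CPM. Beside these, Cd53 was at 7.99 ± 1.3 CPM, and the leukocyte gene Ptprc at 0.0423 ± 0.037 CPM. Of 6 adipocyte markers, 3 rose, 2 fell and 1 did not pass (3 and 2 also when adjusted over the list alone; camera adjusted p = 0.12). The adipocyte regulator Pparg rose 2.23-fold to 7.12 ± 0.73 CPM, and Lpl, which encodes lipoprotein lipase, fell 1.95-fold to 19.7 ± 1.9 CPM. Of 11 neural and glial markers, 2 rose, 5 fell and 4 did not pass (2 and 5 also when adjusted over the list alone; camera adjusted p = 0.096). Gap43, a growth cone gene, fell 2.22-fold, Map2 2.28-fold and Sox10, a neural crest factor, 2.49-fold. Of 11 cartilage and bone markers, 2 rose, 1 fell and 8 did not pass (2 and 1 also when adjusted over the list alone; median -0.10, mean 0.00, direction up, camera adjusted p = 0.89), and Comp rose from 0.895 ± 0.3 to 3.12 ± 0.21 CPM. Of 6 skeletal muscle markers, 1 rose (1 also when adjusted over the list alone; camera adjusted p = 0.7), Acta1, from 267 ± 46 to 524 ± 110 CPM (adjusted p = 0.00199, 0.0687 without culture 5). Over the alternative settings this p was 2.63e-07 to 0.0687. Myl4, of the same list, differed by 0.44 (adjusted p = 0.0558, higher in 2 of 3 cultures, 0.0316 with the block, 0.0155 without the WM-2474 240 h library of culture 5). This p ran from 0.0155 to 0.554 over the alternative settings. Of 6 endothelial and 7 epithelial and mesothelial markers, 1 fell and 1 rose, in that order (0 and 0 when adjusted over the list alone; camera adjusted p = 0.93, with median 0.00, mean 0.07 and direction down, and 0.71). These calls, of Kdr and Krt7, were lost in some alternative settings, with adjusted p of 0.0242 to 0.386 and 0.00171 to 0.253. Msln differed by 0.97 (adjusted p = 0.171, 0.0224 with DESeq2, 0.015 with the block). Across the alternative settings the same p was 0.015 to 0.496.

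Whether the effect of WM-8014 differed between 240 h and 96 h was tested as an interaction of compound and time. The log2 fold change was lower at 240 h than at 96 h for 43 of 45 mitotic genes and 34 of 48 replication genes (43 and 38 when adjusted over the list alone). Their camera adjusted p values were 4.7e-84, and 0.033 with an estimated correlation, and 1.8e-34, against adjusted p = 0.085 with an estimated correlation. The log2 fold change at 240 h minus that at 96 h was -1.13 for Mki67 (SE 0.0775, adjusted p = 2.06e-07), and for Cdkn2a and Cdkn2b it was 0.55 (SE 0.0778, adjusted p = 0.000173) and 0.56 (SE 0.0593, adjusted p = 3.12e-06). In all, 728 genes had a higher and 782 a lower log2 fold change at 240 h, and of these 1510 the effect was larger with the same sign for 992, smaller with the same sign for 34 and of opposite sign for 484, 62 of them called at both times. The counts were 352, 315 and 415 higher and 533, 409 and 452 lower without cultures 5, 6 and 7, and 240 and 346 without the WM-2474 96 h libraries of cultures 6 and 7.

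**Figure D3:**
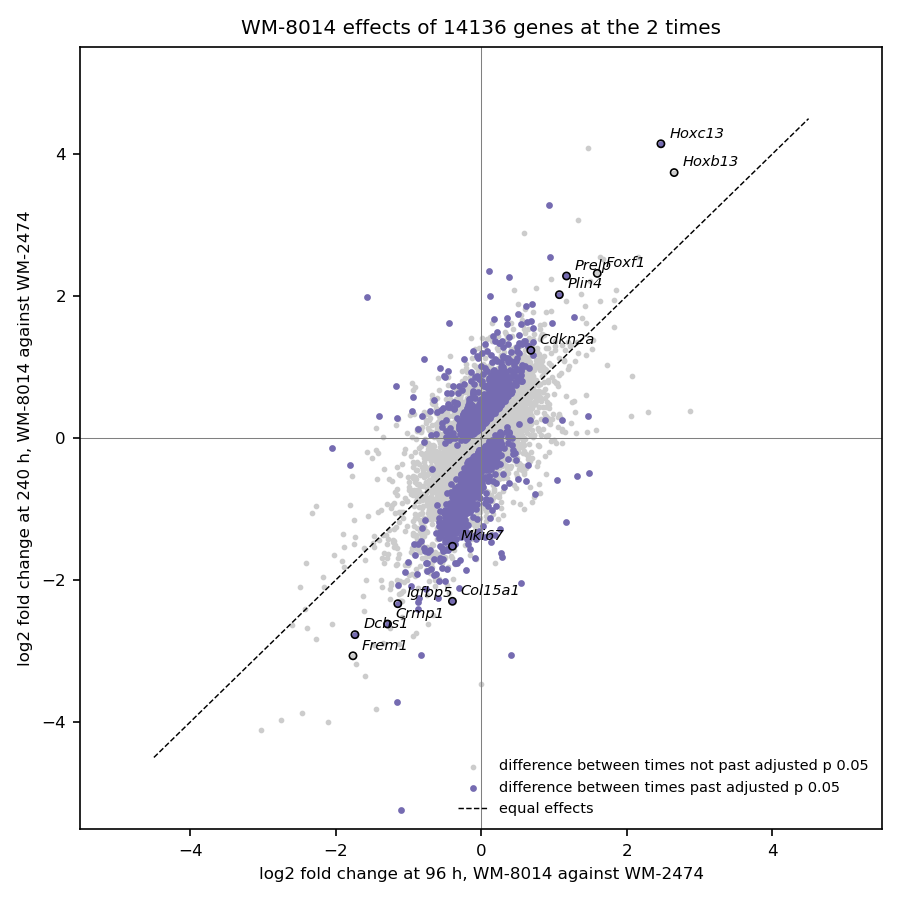
Log2 fold change with WM-8014 against WM-2474 at 96 h (horizontal) and 240 h (vertical) for 14136 genes. Purple points passed an adjusted p of 0.05 for the difference between times, the dashed line marks equal effects, and across genes, which are not independent replicates, Pearson's r was 0.667.

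Of the other lists, 11 of 28 p53 targets had a higher log2 fold change at 240 h and 1 a lower one (15 and 2 when adjusted over the list alone). Camera gave 1.6e-05 as the adjusted p, against adjusted p = 0.24 with an estimated correlation. Mdm2 differed by 0.53 (adjusted p = 4.79e-06) and Ccng1 by 0.35 (adjusted p = 5.2e-05), with Ckap2 at -0.57 (adjusted p = 0.00011). Of 17 contractile genes, 9 had a higher effect at 240 h (12 higher when adjusted over the list alone). Camera gave 4.6e-09 as the adjusted p, against adjusted p = 0.24 with an estimated correlation. Des differed by 1.07, Tpm2 by 0.43 and the myosin light chain gene Myl9 by 0.37 (adjusted p = 3.99e-05). Of 22 stress response genes, 6 had a lower effect (7 when adjusted over the list alone). Camera gave 0.0033 as the adjusted p, against adjusted p = 0.24 with an estimated correlation. Among its members Slc7a5 differed by -0.49 (adjusted p = 4.76e-05) and Trib3 by -0.51. Of 30 secreted factors, 4 were higher and 1 lower (6 and 2 when adjusted over the list alone). Camera gave 0.032 as the adjusted p, against adjusted p = 0.24 with an estimated correlation. Of 15 imprinted genes, 2 were lower (2 also when adjusted over the list alone), Peg3 at -0.63 and Igf2r at -0.42. Camera gave 0.04 as the adjusted p, against adjusted p = 0.46 with an estimated correlation and 0.471 without culture 5. The p ranged from 0.00479 to 0.471 over the alternative settings. The lists of matrix and interferon-stimulated genes each had a camera adjusted p of 0.052, which was 0.0235 and 0.000562 for the matrix list and 2.79e-05 and 0.00751 for the interferon list without cultures 6 and 7 in turn, with ranges of 0.000562 to 0.739 and 2.79e-05 to 0.936 over the alternative settings. That of epithelial and mesothelial markers was 0.18, 0.0316 with the block, 0.0246 without culture 6, and 0.0246 to 0.739 over the alternative settings.

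Among single genes that differed between times were Hoxc13 (1.68, SE 0.336, adjusted p = 0.00211) on the higher side and Col15a1 (-1.90, SE 0.166, adjusted p = 2.26e-06), Tenm4 (-1.65, adjusted p = 0.000168) and Lrrn3 (-1.51, adjusted p = 1.47e-05) on the lower. Col15a1 was at 10.5 ± 2.1 and 8.31 ± 0.86 CPM at 96 h. Crmp1 differed by -1.33 (adjusted p = 0.000247), Nes by 0.81 (adjusted p = 0.00207), Lpl by -1.06 and Plin4 by 0.95. Among the genes of cell-cycle exit, Lmnb1 differed by -0.98, Melk by -0.88, Top2a by -0.92, Ezh2 by -0.57 and Cdkn1a by 0.26 (adjusted p = 0.00242, 0.0792 without the WM-2474 96 h libraries of cultures 6 and 7). Over the alternative settings this p was 0.000188 to 0.0792. For Kat6a (-0.14, 95% interval -0.26 to -0.02, adjusted p = 0.125), Kat6b (0.08, 95% interval -0.07 to 0.23, adjusted p = 0.538) and E2f2 (-0.86, adjusted p = 0.139) the difference did not pass. Foxf1 differed by 0.73 (adjusted p = 0.0592, 0.0396 with the block, 0.013 without the WM-2474 240 h library of culture 5). This p ran from 0.013 to 0.544 over the alternative settings. Of the calls at each time, 1153 genes were higher at both, against 327 for independent lists of those sizes, and 1260 were lower at both, against 359.

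The change from 96 h to 240 h under WM-2474 shows what happened over time without the inhibitor. No untreated group was sequenced, so time in culture and the length of exposure to WM-2474 cannot be told apart. By camera, with a preset and with an estimated correlation, contractile and matrix genes rose and genes of cholesterol synthesis and adipocytes fell. All 17 contractile genes rose (17 when adjusted over the list alone). Camera gave 1.9e-36 as the adjusted p, and adjusted p = 0.015 with an estimated correlation, and Acta2 rose from 2670 ± 60 to 5490 ± 210 CPM. All 25 cholesterol genes fell (25 when adjusted over the list alone). Camera gave 2.3e-100 as the adjusted p, and adjusted p = 0.0023 with an estimated correlation, and Lss fell from 264 ± 5.5 to 107 ± 3.5 CPM. Of 14136 genes, 2800 rose and 2697 fell (38.9%), and 1454 and 1256 without the WM-2474 96 h libraries of cultures 6 and 7. Of 37 matrix genes, 29 rose, 2 fell and 6 did not pass (30 and 3 when adjusted over the list alone). Camera gave 1.1e-33 as the adjusted p, and adjusted p = 0.01 with an estimated correlation. Col15a1 rose 6.09-fold (adjusted p = 1e-12) and Thbs1 from 10100 ± 410 to 17600 ± 400 CPM. Of 45 mitotic genes, 44 fell (44 when adjusted over the list alone). Camera gave 9.1e-30 as the adjusted p, against adjusted p = 0.11 with an estimated correlation, and Mki67 fell by 0.63 on the log2 scale. Of 48 replication genes, 42 fell (43 when adjusted over the list alone). Camera gave 5.3e-11 as the adjusted p, against adjusted p = 0.25 with an estimated correlation. Of 6 adipocyte markers, 6 fell (6 when adjusted over the list alone). Camera gave 4.7e-06 as the adjusted p, and adjusted p = 0.03 with an estimated correlation, and Plin4 fell by 1.59 on the log2 scale. Of 28 p53 targets, 17 rose and 2 fell (17 and 2 also when adjusted over the list alone). Camera gave 6.2e-08 as the adjusted p, against adjusted p = 0.11 with an estimated correlation, and Cdkn1a rose from 391 ± 9.2 to 684 ± 0.6 CPM. Of 7 epithelial and mesothelial markers, 5 fell (5 also when adjusted over the list alone). Their median log2 fold change was -1.44, with a camera adjusted p of 0.0079, against adjusted p = 0.25 with an estimated correlation. Of 6 endothelial markers, 4 fell (4 also when adjusted over the list alone), with a median of -1.08. Camera gave 0.046 as the adjusted p, against adjusted p = 0.25 with an estimated correlation, 0.0632 with the block, and 0.104, 0.0544 and 0.166 without cultures 5, 6 and 7, in a range of 0.0318 to 0.246 over the alternative settings. Cdkn2a rose by 0.87 (adjusted p = 1.92e-09). Among the largest changes were rises of Heyl (10.4-fold, adjusted p = 2e-09) and Sema5b, an axon guidance gene (6.58-fold), and falls of Arhgap36 (10.5-fold, adjusted p = 5.32e-07), Kng2 (8.1-fold), the leptin receptor gene Lepr (7.82-fold), Enpep (6.94-fold) and Msln (6.25-fold). The log2 fold change of Heyl went from 3.38 to 5.03 without the WM-2474 96 h libraries of cultures 6 and 7. Misp3, at 152 ± 64 and 268 ± 18 CPM with WM-8014 at the respective times, was among the 5 highest under WM-2474 with an adjusted p of 0.0487. This became 0.133 or 0.108 without the WM-2474 96 h library of culture 6 or 7, and 0.0817, 0.0898 or 0.0932 without the WM-2474 240 h library of culture 5, 6 or 7. It was 0.162 without both WM-2474 96 h libraries of cultures 6 and 7, 0.174 with the WM-2474 libraries alone in the fit, and 0.0678 with no filter on low counts. Across the alternative settings the same p was 5.45e-06 to 0.323. The log2 fold change of Misp3 went from 3.31 to 7.84 without the WM-2474 96 h library of culture 5, 2.72 without that of culture 6, 2.29 without that of culture 7 and 1.21 without the latter 2, and it was 6.83 with limma-voom.

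Under WM-8014, 3504 genes rose and 3527 fell from 96 h to 240 h (49.7%), 394 and 650 of them by at least 2-fold. Mitotic genes fell in 44 of 45 cases and replication genes in 47 of 48 (44 and 47 when adjusted over the list alone), with camera adjusted p values of 3.6e-73 and 1.2e-28, and 0.014 and 0.049 with an estimated correlation. Mki67 fell by 1.76 on the log2 scale, from 197 ± 11 to 57.9 ± 4.1 CPM, and the kinetochore gene Cenpf by 1.66. Contractile genes rose in 17 of 17 cases and cholesterol genes fell in 25 of 25 (17 and 25 when adjusted over the list alone), with camera adjusted p values of 9.9e-40 and 1.8e-56, and 0.014 for each with an estimated correlation. Of 37 matrix genes, 29 rose and 3 fell (29 and 3 also when adjusted over the list alone). Camera gave 6e-16 as the adjusted p, and adjusted p = 0.049 with an estimated correlation. Of 28 p53 targets, 21 rose and 2 fell (22 and 3 when adjusted over the list alone). Camera gave 1.4e-11 as the adjusted p, against adjusted p = 0.051 with an estimated correlation. Of 6 endothelial markers 4 fell, and of 7 epithelial and mesothelial markers 3 fell (4 and 3 also when adjusted over the list alone), with medians of -0.85 and -1.30 and camera adjusted p of 0.36 and 0.32. Cdkn2a rose by 1.43 (SE 0.0546, adjusted p = 1.01e-12), Cdkn2b by 0.77 and Cdkn1a by 1.07. Among the largest changes were rises of Ccdc81 (7.21-fold, adjusted p = 3.65e-09), Cxcr6 (6.49-fold), the natriuretic peptide gene Nppb (6.31-fold), Galnt16 (6.14-fold) and Sprr2k (7.7-fold), whose reads may be shared with other Sprr2 genes. Ppl, which encodes the desmosomal protein periplakin, fell 7.17-fold, Lrrn3 6.16-fold, Arhgap36 5.84-fold and Kng2 5.67-fold, while Enpep fell 16-fold. Its log2 fold change was -3.34 without the WM-8014 240 h library of culture 6 and -3.27 with all libraries thinned to the smallest total.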

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

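The results listed here are those whose effect of WM-8014 differed between 96 h and 240 h by a test of the difference itself, the interaction in edgeR for genes and camera for lists. The interaction and the count over other splits were chosen before the result was seen, and the run without the WM-2474 96 h libraries of cultures 6 and 7 after it. Values are the log2 fold change at 240 h minus that at 96 h. In all, 728 genes had a positive and 782 a negative difference.

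The genes of cell-cycle exit that were always named gave 0.55 for Cdkn2a, 0.56 for Cdkn2b, 0.26 for Cdkn1a, -0.57 for Ezh2, -0.88 for Melk, -0.98 for Lmnb1, -1.13 for Mki67 and -0.92 for Top2a. For Cdkn1a the adjusted p of 0.00242 became 0.0792 without the WM-2474 96 h libraries of cultures 6 and 7, in a range of 0.000188 to 0.0792 over the alternatives. Among other genes of replication and mitosis, the difference was -1.06 for Uhrf1, -0.48 for Dnmt1, -0.89 for Plk1 and -0.97 for Cenpf. Of the p53 list, it was 0.53 for Mdm2, 0.35 for Ccng1 and -0.57 for Ckap2.

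Contractile genes gave 0.37 for Myl9, 0.43 for Tpm2 and 1.07 for Des, and matrix genes -0.82 for Fbln1 and 0.45 for Thbs1. Of the stress response list, Slc7a5 gave -0.49 and Trib3 -0.51, and of the imprinted list Peg3 gave -0.63 and Igf2r -0.42. Single genes were Hoxc13 at 1.68, Crmp1 at -1.33, Col15a1 at -1.90, Tenm4 at -1.65, Lrrn3 at -1.51, the neural marker Nes at 0.81, and the adipocyte markers Lpl at -1.06 and Plin4 at 0.95.

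The lists that differed between times had camera adjusted p values of 1.8e-34 for S phase and DNA replication, 4.7e-84 for G2 and mitosis, 1.6e-05 for p53 targets, 0.032 for secreted factors of senescent cells, 4.6e-09 for contractile genes, 0.0033 for the stress response and 0.04 for imprinted genes. With an estimated correlation the mitotic list passed (adjusted p = 0.033) and the others did not, with adjusted p = 0.085 for replication, 0.46 for imprinted genes and 0.24 for each of the rest.

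Of 100 splits of the libraries into groups of the same sizes, 1, the real one, gave as many genes for the interaction at an adjusted p under 0.05. The real value was 1510 and the highest of the others 1293. That value came from a split that kept the real groups at 240 h and mixed the 96 h libraries. The 9 such splits gave 1071 to 1293 genes, and at an unadjusted p under 0.05 they gave 3309 to 3744, above the 3305 of the real split. Each of these splits exchanges 1 library between the groups at 96 h, which leaves part of the effect of WM-8014 there and widens its spread, so the effect at 240 h is set against a smaller one. They hold real effects, so the count of splits does not show whether chance can be excluded for a difference between 2 effects. The 9 splits that kept the real groups at 96 h gave 0 to 2 genes, and the 81 that mixed both times gave 0. With 10 splits of 3 against 3, no share under 0.05 can be had for the other comparisons. Their real values were 3218 genes at 96 h, 6027 at 240 h, 5497 over time under WM-2474 and 7031 over time under WM-8014, each reached by 1 split, and the highest of the other splits was 0 by edgeR in each. At an unadjusted p under 0.05 the highest of the others was 920, 905, 954 and 621 genes in that order, against 4915, 7085, 6534 and 7809. At 96 h, where the numbers pair the libraries, the real split parts all 3 pairs, as do 3 others, which gave 0 genes by edgeR and 337, 542 and 439 at an unadjusted p under 0.05, and the other 6 part 1 pair.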

How the results depend on the processing

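The thinned counts, the runs without the 20 most abundant genes, those without the WM-2474 96 h libraries of cultures 6 and 7, and all alternatives of the lists over time were chosen after the result was seen. Of 356 values of named genes, 319 were called, and 273 kept call and direction in every alternative run for them. Of 115 list results, 49 did. No called value changed direction.

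The counts of called genes moved by over 1.5 times in only 2 kinds of alternatives. Without the WM-2474 96 h libraries of cultures 6 and 7, which leaves 1 library in that group, 432 genes were higher and 437 lower at 96 h, 240 and 346 for the interaction, and 1454 and 1256 over time under WM-2474. Fewer samples are part of that setting, and no other cause was tested. Leaving out 1 library or 1 culture gave 847 to 1340 genes higher and 903 to 1422 lower at 96 h, and 315 to 802 higher and 409 to 801 lower for the interaction, and the cause was not tested beyond the loss of libraries. The same alternatives gave 2161 to 2795 higher and 2193 to 2994 lower at 240 h, 1995 to 2794 and 1821 to 2469 over time under WM-2474, and 2798 to 3283 and 2672 to 3235 under WM-8014.

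With DESeq2 in place of edgeR, 1113 and 1345 genes were called higher and lower at 96 h and 2557 and 2582 at 240 h, and with limma-voom 1609 and 1735, and 3080 and 3054. Other scaling moved the share of higher calls by less than 10 percentage points, at 96 h from 48 to 45.4% with DESeq2-type size factors. Of the named genes, 34 calls were lost without culture 7, 27 without culture 6, 24 without culture 5, and 55 without the 2 WM-2474 96 h libraries of cultures 6 and 7.

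Of the lists, 7 passed at 96 h, 7 at 240 h and 7 for the interaction. With camera and an estimated correlation these were 0, 1 and 1, since genes of a list that vary together add to the variance of the list, and the lists that passed were those of mitotic genes. At 240 h, 15 lists passed with fry, which tests the list's own direction and does not set it against other genes. Leaving out a culture gave 6 to 9 lists at 96 h, 7 to 8 at 240 h and 6 to 10 for the interaction.

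With the culture number as a replicate block, the pairing gave 1737 genes higher and 1853 lower at 96 h. The block changed the calls given beside Stag3, Brpf3, Col11a2, G6pdx, Wt1, Msln, Myl4 and Foxf1, and of the lists of matrix genes and developmental factors at 96 h, imprinted genes at 240 h, and epithelial and mesothelial markers for the interaction. It also ended the call of endothelial markers over time under WM-2474 (adjusted p = 0.0632, in a range of 0.0318 to 0.246), and it changed no other call of a named gene or list.

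In the 12 libraries, 3 reads corresponded to 0.0654 to 0.296 CPM. With all libraries thinned to the smallest, 1220 genes were higher and 1360 lower at 96 h, and 16 calls of named genes were lost, among them Stag3 at 96 h (adjusted p = 0.0982, in a range of 4.65e-11 to 0.388 over the alternatives). The cause of these losses was not tested. The interaction was the comparison with the lowest recovery, where the test recovered 28.36% of the smallest simulated changes and 55.22% of those of 1.5-fold.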

Other observations

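Of the tests in this part, the comparison of Y-linked transcripts with their X-linked homologues was chosen before its result was seen, and the tests of Misp3, of male cells, of macrophages, of time in culture and of Hox genes were chosen after it. By camera, lists of lysosomal, secreted, interferon-stimulated and imprinted genes also moved from 96 h to 240 h under both compounds, and none of these 8 results passed with an estimated correlation. Of 29 lysosomal genes, 17 rose and 2 fell from 96 h to 240 h under WM-2474 (camera adjusted p = 0.0039, and adjusted p = 0.27 with an estimated correlation), and 17 rose and 4 fell under WM-8014 (camera adjusted p = 0.004, and adjusted p = 0.38 with an estimated correlation). Ctsk, a collagen-degrading cathepsin, rose from 91.4 ± 4.2 to 167 ± 6 CPM and from 139 ± 8.2 to 224 ± 19 CPM. Of 30 secreted factors, 18 rose and 5 fell under WM-8014 (camera adjusted p = 0.0028, and adjusted p = 0.078 with an estimated correlation), and Plau rose from 101 ± 7.2 to 241 ± 30 CPM. Under WM-2474, 11 rose and 7 fell (camera adjusted p = 0.043, adjusted p = 0.25 with an estimated correlation, 0.105 with no filter on low counts, 0.104 without culture 5 and 0.126 without culture 7, in a range of 0.00466 to 0.246 over the alternatives).

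Of 23 interferon-stimulated genes, 17 fell over time under WM-8014 (camera adjusted p = 0.00074, and adjusted p = 0.49 with an estimated correlation), and 7 fell under WM-2474 (camera adjusted p = 0.0083, adjusted p = 0.43 with an estimated correlation, and 0.0602 without culture 7, in a range of 5.6e-05 to 0.428 over the alternatives). Gbp2, a guanylate-binding protein, fell from 11.3 ± 0.48 to 4.14 ± 0.36 CPM and from 7.33 ± 0.88 to 3.25 ± 0.65 CPM. Of 15 imprinted genes, 10 fell and 2 rose under WM-8014 (camera adjusted p = 0.00058, and adjusted p = 0.14 with an estimated correlation), and 8 fell and 3 rose under WM-2474 (camera adjusted p = 0.0069, and adjusted p = 0.25 with an estimated correlation), with Peg3 falling 2.77-fold and 1.79-fold. Of 6 adipocyte markers, 5 fell under WM-8014 (camera adjusted p = 0.00056, and adjusted p = 0.053 with an estimated correlation). Under WM-2474 camera also called Hox genes and other developmental factors lower, each at an adjusted p of 0.046 and each at adjusted p = 0.25 with an estimated correlation. Without culture 7 these were 0.0822 and 0.0865, in ranges of 0.0111 to 0.246 and 0.0144 to 0.246.

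Misp3, Stag3, Ntn3 and Lrrn2 were low in the WM-2474 96 h libraries of cultures 6 and 7, with Misp3 at 0.724 and 0.943 CPM there and 89 CPM in culture 5 of the same group. Depth is excluded, since 56 Misp3 reads were seen in the 2 libraries where the lowest level of the other 10 would give 5000. RNA of a WM-2474 240 h library in the culture 5 library would have to make up a share of 0.43, and genes at least 2-fold apart between those groups were displaced in it by a median of 0.0142 (170 genes, SE 0.013), with 0.0251 (616 genes, SE 0.0072) at 1.5-fold, a threshold added after the first was seen, so this source is excluded. RNA of a WM-8014 96 h library would need a share of 0.585. Only 27 genes were 2-fold apart, with a median displacement of 0.222 (SE 0.07, upper quartile 0.415). At 1.5-fold, 157 genes gave 0.134 (SE 0.036, upper quartile 0.375). Both values argue against this source at the needed share. It was not excluded by the rule used, because 0.222 is not below 0.5 of that share by 2 SE. Other sources of RNA were not tested. No biological explanation was tested, since the labels name nothing that separates culture 5 from cultures 6 and 7.

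All 12 libraries, labelled female, held Ddx3y (96.2 to 124 CPM), Eif2s3y (60.5 to 77.7), Kdm5d (27.6 to 33.1) and Uty (27.6 to 32.9), with 17 Xist reads in all. Reads of the X-linked homologues are excluded as the source, because at most 0.116% of the 50-base stretches of a Y-linked gene's transcripts also lie in its homologue, against a lowest ratio of Y-linked to X-linked reads of 22.2%. Male cells in every culture are a candidate explanation, and the values of the 4 Y-linked genes argue against cultures of female cells alone. That 12 of 12 libraries held all 4 Y-linked genes with Xist at or below 1 CPM restates the pattern and is no independent test of it. Whether female cells were also present was not tested, and Xist was at most 0.203 CPM in a library.

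Cd53, Itgb7 and H2-DMb1, known from white blood cells and grouped here after their values were seen, gained 1.62, 5.61 and 2.05 CPM with WM-8014 at 96 h. If macrophages were the source, their listed markers would be expected to gain at least as much as Cd53. A set of 9 markers, Ptprc, Tyrobp, Fcer1g, C1qa, C1qb, C1qc, Cd52, Aif1 and Adgre1, was run first and gained 0.0343 CPM (SE 0.18), with 3 reads of Tyrobp and 34 of Ptprc in all 12 libraries. All 14 markers, run after because the 9 left out Lyz2, gained 2.66 CPM (SE 0.61), from 8.16 to 10.8, of which Lyz2 gave 1.07, Csf1r 0.928 and Cd14 0.83. At 96 h the 9 thus gained less than their SE. At 240 h they were at 0.56 ± 0.21 CPM with WM-2474 and 0.543 ± 0.25 CPM with WM-8014. Cd53 gained 6.11 CPM there, and all 14 markers gained 5.21 CPM. The 9 markers, flat at both times, argue against macrophages as the source of the Cd53 gain. The 14 do not decide, because their gain at 96 h lies in Lyz2, Csf1r and Cd14, of which Lyz2 alone passed. The fibroblasts' own level of these 3 is not known, so macrophages are not excluded.

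A first hypothesis was that WM-8014 carried further the change that time in culture brings under WM-2474. Across 14136 genes, which are not independent, that change and the WM-8014 effect at 240 h had a Pearson r of 0.0274, judged first. Both use the WM-2474 240 h libraries with opposite signs. In 20 simulations of unchanged groups r was -0.447 and the covariance -0.0126, against 0.00568 seen. The r corrected for these was 0.102, between bounds of 0.1 (reject) and 0.3 (keep) set after the first r was seen. Its error was not estimated and it lies close to 0.1, so it does not decide. Of called genes, 1035 were higher in both (593 if independent), 1002 lower in both (578) and 998 opposite. Called genes thus mostly agreed in sign, and the hypothesis stays open. The correction is approximate, as it sets differences of mean log2 CPM against edgeR fits. At 96 h the corrected r was 0.0056 (0.116 before, 0.517 simulated).

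A second hypothesis was that Hox genes of paralogue group 13, at the end of their clusters, respond more to WM-8014 than the other Hox genes. At 240 h the 3 measured, Hoxc13, Hoxb13 and Hoxd13, had a mean log2 fold change of 3.33, against -0.163 for 30 others (-0.804 to 1.01). The exact one-sided permutation p over the 33 genes was 0.00018, the smallest that 5456 permutations can give. The group was chosen after Hoxc13 and Hoxb13 had been seen to be the highest, which largely fixed this p in advance, so the test decides nothing about cluster ends. Hoxd13 was at 0.156 ± 0.19 and 0.645 ± 0.15 CPM. Hoxc11, at 0.396 ± 0.12 and 0.766 ± 0.12 CPM, did not pass (adjusted p = 0.104). Too low to be tested were Hoxa13 (0.0327 ± 0.029 and 0.195 ± 0.13 CPM), Hoxc12 (0.147 ± 0.087 and 0.659 ± 0.3), Hoxd11 (0.189 ± 0.17 and 0.0874 ± 0.026) and Hoxd12 (at most 0.0336 in both groups).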
